A study of Homo sapiens with 24 samples.

How the data were processed

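RNA of 24 samples in 8 groups of 3 was measured on 1-colour Affymetrix arrays, 1 array per sample. The authors deposited probe set intensity values made with RMA, per the submitters' processing notes. The software, its version and whether all arrays were processed together are not given in the sources used here. RMA corrects the background, brings arrays to shared quantiles and summarises the probes of a set, and it compresses differences near the background. The deposited intensity values are on a linear scale, from 4.411 to 20899.1 with 0 missing, so log2 was taken before any test. No column of the table was left out, and no 2 arrays were identical.

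The table held 54675 probe sets. The probe table used for names listed 42898 of them, 41097 with 1 gene symbol and 1801 with several, and the 11777 not listed were unnamed here. Each gene was represented by the probe set naming only that gene with the highest mean over all 24 arrays, which gave 19775 genes, of which 10523 had more than 1 probe set. By gene ID, 19735 matched the RefSeq table of assembly GRCh38.p14, which was used for names alone, and 0 symbols needed an update. No filter on dim genes was applied. No depth exists for arrays, and their number limits the precision.

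Groups were taken from the sample titles. A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), with 4.57 prior and 20.57 total degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes tested within each of 11 comparisons. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. For 26 gene lists, camera was run with a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Lists, tests, thresholds, named genes and the alternatives were fixed before the data were examined, except where stated. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

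The text names, per comparison, the called genes with the highest and lowest log2 fold changes, up to 10 each way and in order of size, whose 3 arrays of 1 group all lay above the 3 of the other (a split that chance gives in 10% of genes), leaving out LOC, orf and clone names, XIST and Y-linked genes. It also names 2 to 8 members of each list assigned to the comparison, those with the largest absolute change and some that did not pass, and, of genes marking a population or protocol, those with the largest smaller fold change, up to 8. Other lists are named where they moved with a group, chosen after their values were seen.

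The gene test was checked on simulated data for APS against hESC over 19775 genes. It recovered 97.5% of 80 genes changed by 1.5 on the log2 scale and 100% of 80 changed by 2, with 0 false calls. A list shifted by 0.5 was called, with 2 of 25 other lists, which share genes with it. The simulated noise was independent between genes. With a fold threshold of 1, false calls were therefore unlikely from the start. The list check says nothing about lists whose members vary together.

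The alternatives were the mean of each gene's probe sets, every probe set separately, a filter on dim genes, a fit on only the 6 arrays compared, the replicate number as a block, another quantile normalization, scaling to housekeeping genes, array weights, a trended robust variance prior, an adjusted p under 0.01, no fold threshold, an estimated correlation for lists, and each array left out in turn. Leaving out DE replicate 1 and Serum replicate 3 together was added after seeing the data.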

Results

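HES3, an established line of human embryonic stem cells, was profiled on 1-colour Affymetrix expression arrays as it was driven into endoderm. The 24 arrays formed 8 groups of 3. These were undifferentiated stem cells (hESC), anterior primitive streak at day 1 (APS), definitive endoderm at day 3 (DE), and anterior foregut (AFG), posterior foregut (PFG) and midgut/hindgut (MHG) at day 7. All of these but hESC carry the protocol label SR1. The 2 remaining groups were day 3 cells from alternative protocols, labelled AFBLy and Serum. Array medians lay between 18.52 and 20.36 on the deposited linear scale, and the number of arrays limits the precision. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

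Replicates were tight. Pearson's r across genes between arrays of 1 group lay between 0.996 and 0.998, where genes are not independent replicates. Pooled over the 8 groups, the median within-group SD of a gene was 0.12 on the log2 scale and the largest 0.478, and the largest SD of a gene within 1 group was 1.11. The first principal component held 33.9% of the variance and separated the 3 day 7 populations from all earlier groups. The second (24.2%) ran from hESC to AFBLy, with Serum beside APS, and the third (13.9%) set MHG apart from the other day 7 populations. DE replicate 1 stood apart from the other 2 DE arrays (SD per array 0.17 and 0.16, against 0.112 between replicates 2 and 3). Serum replicate 3 had a lower top end, with a highest value of 14474 against 18244 and 19672 in the other 2.

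**Figure D1:**
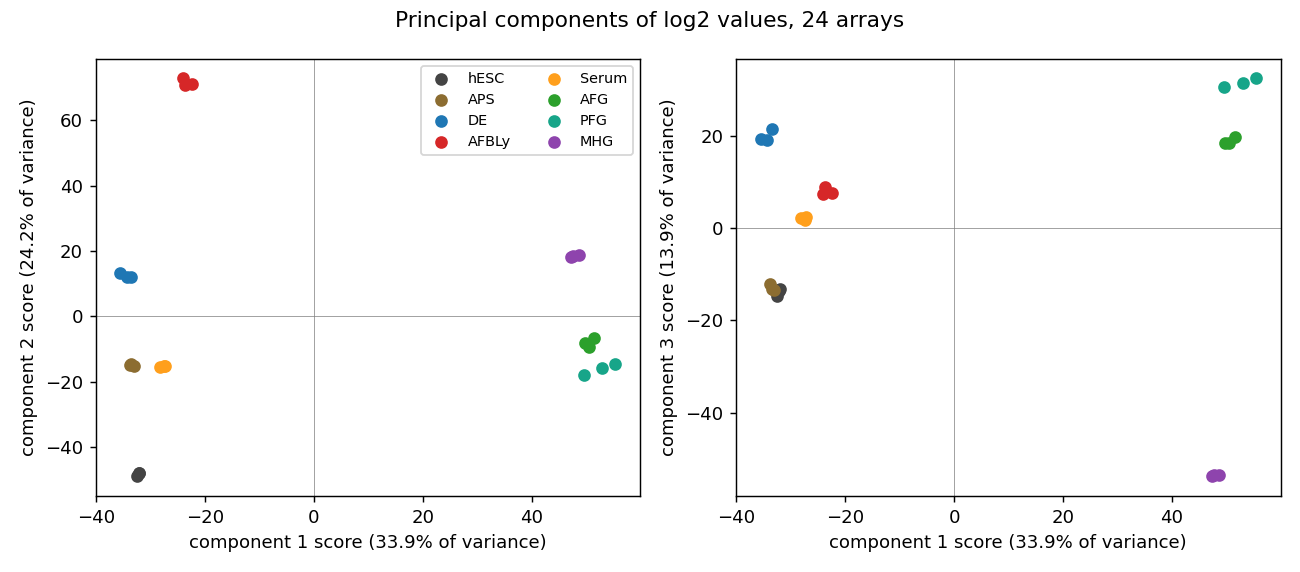
Scores of the 24 arrays on principal components of log2 values, coloured by group, with component 1 on each horizontal axis and components 2 and 3 on the vertical axes (unitless scores, percent of variance in the axis labels). The 3 arrays of each group lie together, and component 1 (33.9%) parts the day 7 populations from the rest.

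A gene was called at a limma adjusted p under 0.05 and an absolute log2 fold change of at least 1. The p threshold removed 0 genes: in each of the 11 comparisons every gene past the fold threshold also had an adjusted p under 0.01, the highest being 0.00775. The fold threshold alone therefore set every count below. It also set which direction held more genes: without it the majority turned in 10 of 11 comparisons, for example from 528 higher and 1000 lower to 4177 and 3734 in MHG against PFG. Fold changes are log2 values with the standard error (SE) of the fit, n = 3 against 3. Each gene's value comes from its brightest probe set: of the 220 highest and lowest genes of the 11 comparisons 124 have other probe sets, and for 40 of these none of the others was called in the same direction. In every list the count adjusted over the list alone equalled the count over all genes tested. Genes of the lists that are not mentioned as measured were not analysed here.

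**Figure D2:**
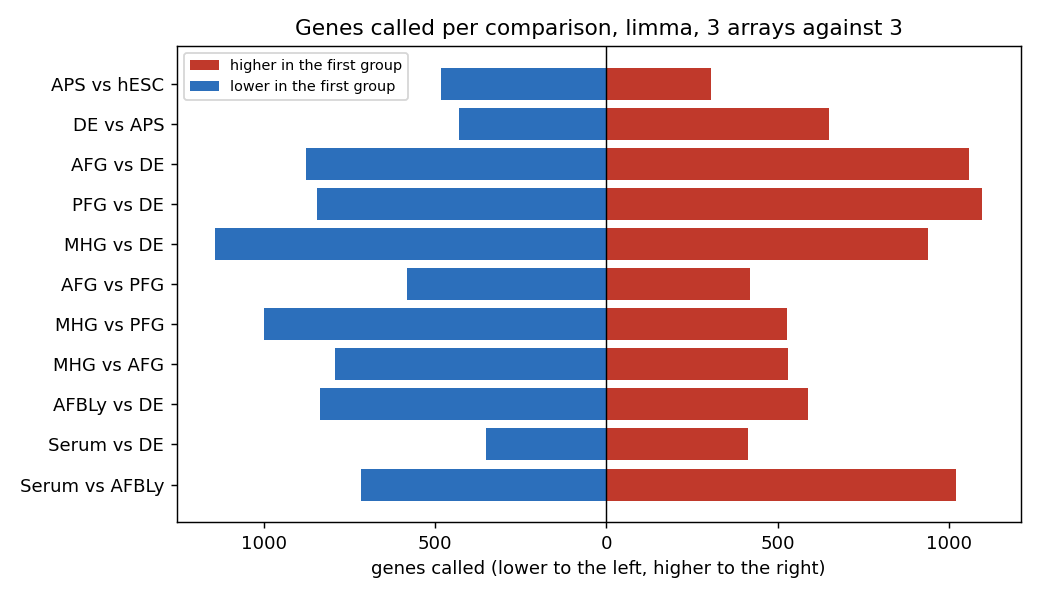
Number of genes called higher (right, red) or lower (left, blue) in the first-named group of each of the 11 comparisons, 3 arrays against 3. Counts run from 764 in Serum against DE to 2081 in MHG against DE.

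The first day of induction, APS against hESC, raised 11 of 16 genes of the primitive streak, the site of the embryo where endoderm and mesoderm arise. DKK4, a secreted WNT antagonist that is itself a WNT target (log2 fold change 6.67, SE 0.18), the streak homeobox gene MIXL1 (5.68, SE 0.12) and DKK1, another WNT antagonist (5.57, SE 0.13), rose most, then CD48 (5.35) and the endoderm factor GATA6 (5.17). FGF4 (5.02), CALCR, the calcitonin receptor (4.57), GSC, an organizer homeobox gene (4.52), and EOMES, a T-box factor (4.44), followed. The steepest falls were in APELA, which encodes a peptide ligand of the apelin receptor (-4.53, SE 0.22), SORBS2 (-4.14), SYTL2 (-4.08), the collagen gene COL12A1 (-3.95) and ACTA1, skeletal actin (-3.84). In all, 306 genes were higher and 483 lower, 789 together.

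Of 16 measured primitive streak genes 11 rose and 0 fell (mean 2.72, limma camera adjusted p = 7e-17). SP5 (3.79), LHX1 (3.75), FOXA2 (3.70) and TBXT, the streak factor brachyury (3.41), were among those 11, while TBX6 (0.05), WNT8A (0.04) and EVX1 (-0.03) did not pass. The definitive endoderm list gained 8 of 18 (mean 1.40, adjusted p = 9.28e-06; adjusted p = 0.12 with an estimated correlation), with SOX17 at 4.01 and HHEX at 3.69. Of 14 WNT response genes 6 rose (adjusted p = 1.7e-06), APCDD1 (3.33) and LEF1 (2.24) among them. Pluripotency genes were split: 6 of 18 fell, led by PODXL (-1.98) and PRDM14 (-1.92), and GDF3 rose (1.59), whereas NANOG (-0.25), LIN28A (-0.06) and SOX2 (-0.93) did not pass. That list's adjusted p was 1.94e-05, and adjusted p = 0.0575 with an estimated correlation. Among mesenchymal genes 3 of 13 rose, CDH11 first (2.61), and 2 fell, TWIST1 (-2.02) first. The list was not called (adjusted p = 0.123). The NODAL list (2 of 9 rose, GSC and CER1 (3.27), adjusted p = 0.611; its mean of 0.70 and median of -0.19 differ in sign) and the epithelial list (0 of 14 changed, with OCLN at -0.86 and CLDN4 at -0.85, adjusted p = 0.296) were not called either. Markers of other cell types moved as well: 5 of 12 fibroblast genes fell and 0 rose (mean -0.91, adjusted p = 9.28e-06), and 4 of 15 trophoblast genes fell (adjusted p = 0.0154; adjusted p = 0.0925 with an estimated correlation).

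From day 1 to day 3, DE against APS, 12 of 18 endoderm genes rose and 8 of 12 BMP response genes fell, the BMP call being lost at an estimated correlation (adjusted p = 0.141). The highest rises were MOBP (5.69, SE 0.14), the apolipoprotein gene APOA2 (5.45, SE 0.21), the protease gene ADAMTS18 (5.17), the gastrin receptor CCKBR (5.13) and PDZK1 (5.11). FGF4 fell by 6.53 (SE 0.12), PDGFRA, a receptor of mesoderm cells, by 3.91, TBXT by 3.91, GABRB2 by 3.85 and CD1D by 3.63. The test called 651 genes higher and 429 lower. Scaling the arrays to housekeeping genes moved the median of all genes from 0.03 to 0.17 and the split to 838 higher and 307 lower, so directions near the threshold are relative to that shift of -0.14.

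Of 18 definitive endoderm genes 12 rose and 0 fell (mean 1.80, limma camera adjusted p = 8.42e-12). STC1, a secreted glycoprotein (4.15), CXCR4, a chemokine receptor used to sort endoderm (4.04), SHISA2 (3.95) and SOX17 (2.45) led, and CER1 (0.84), GATA6 (0.83) and RIPPLY1 (0.08) did not pass. In the BMP response list 8 of 12 genes fell, ID1 (-2.20), ID2 (-2.19) and ID3 (-1.73) first (adjusted p = 2.12e-06; adjusted p = 0.141 with an estimated correlation). In the WNT list 3 of 14 fell, among them DKK4 (-3.36) and LEF1 (-2.66), while LGR5, a receptor of R-spondins, rose (3.56), with adjusted p = 0.00928 and adjusted p = 0.141 with an estimated correlation. In the streak list SP5 fell (-2.45) and LHX1 rose (1.18), in the mesoderm list WNT5A fell (-2.77), in the NODAL list LEFTY1 rose (1.54), and in the pluripotency list GDF3 fell (-2.99) and PODXL rose (1.73). The streak list (2 rose, 4 fell of 16, adjusted p = 0.16), the mesoderm list (4 of 19 fell, adjusted p = 0.285, mean -0.48 but median 0.03), the NODAL list (1 of 9 rose, adjusted p = 0.545) and the pluripotency list (1 rose, 1 fell of 18, adjusted p = 0.25) were not called. NANOG (-0.56) and LIN28A (0.12) did not pass.

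**Figure D3:**
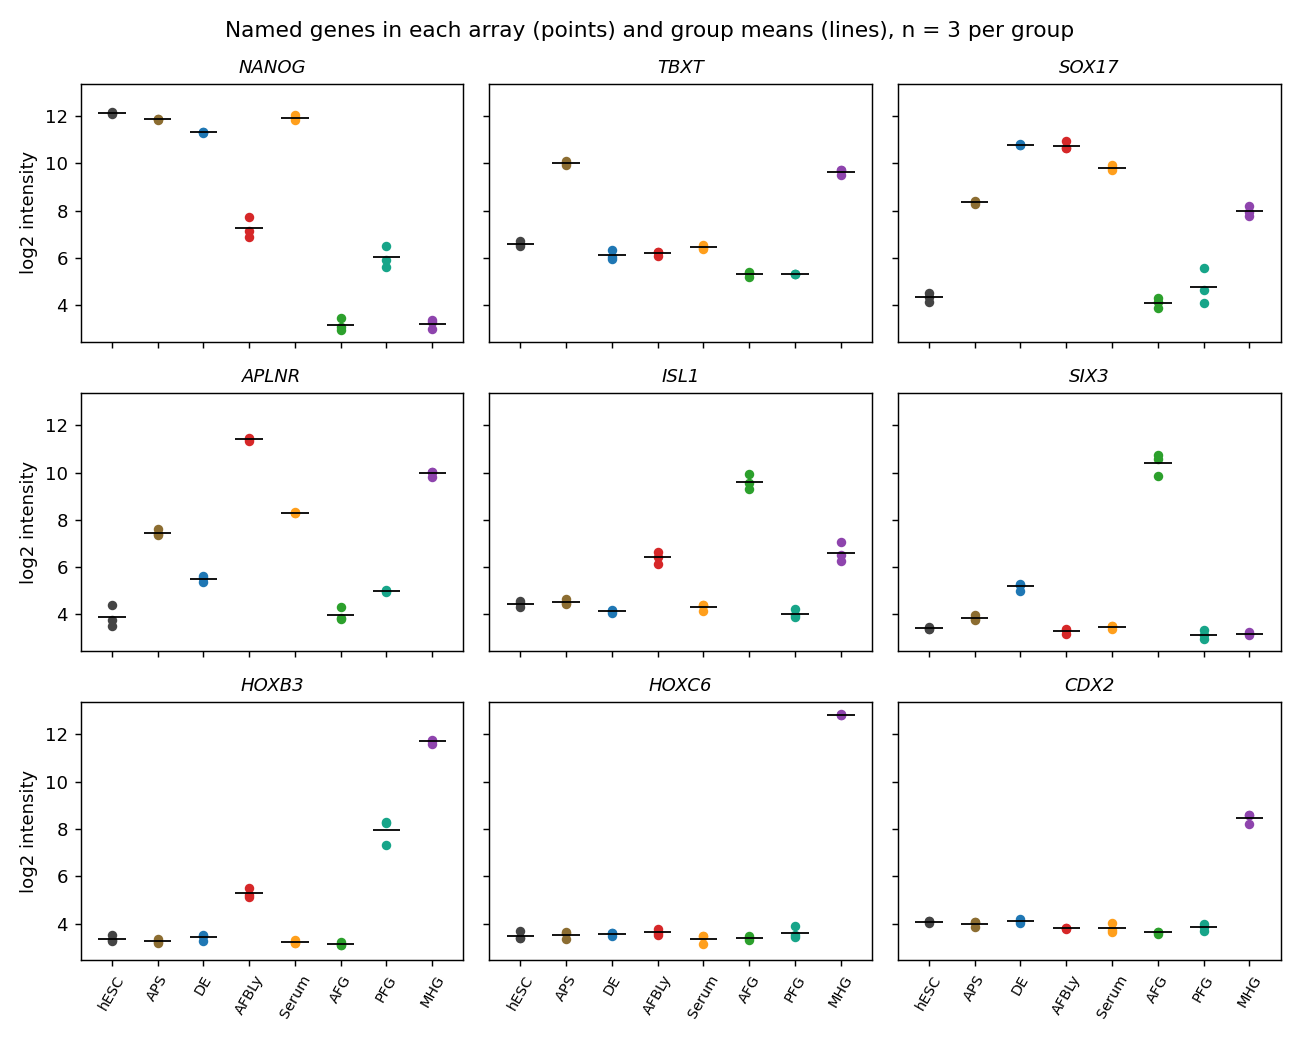
Log2 intensity (vertical axes) of 9 named genes in each array (points) with group means (lines), n = 3 per group. NANOG remains high through day 3 in the SR1 and Serum groups, and HOXC6 is high in MHG, where its mean is 12.83.

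Patterning to anterior foregut, AFG against DE, lowered 7 of 9 genes that answer to NODAL, a signal of the early endoderm, and 12 of 18 endoderm genes, the endoderm call being lost at an estimated correlation (adjusted p = 0.073). Both lists also fell in PFG and MHG against DE, so these falls are not particular to AFG. GREB1L (6.89, SE 0.12), the protocadherin gene PCDH8 (6.34, SE 0.23), PAPLN (6.13), the homeobox gene IRX1 (5.96) and FAM241A (5.67) rose most. No other probe set of GREB1L, PAPLN or FAM241A was called, so their rank rests on 1 probe set each. The same holds for PLSCR2 below. It also holds for GATA6 and CALCR in APS against hESC, and for ADAMTS18 and CCKBR in DE against APS. HOXB3 in MHG against DE, FRMD4B in AFBLy against DE and LRFN5 in Serum against DE are further examples. The NODAL antagonists LEFTY1 (-9.95, SE 0.17) and CER1 (-9.30, SE 0.16) fell most, followed by the receptor gene ERBB4 (-8.49), PLSCR2 (-8.33), NANOG (-8.14) and EOMES (-7.96). The test called 1058 genes higher and 878 lower, a majority that turned with another quantile normalization (954 higher, 962 lower).

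Of 11 anterior foregut genes 6 rose (mean 1.53, limma camera adjusted p = 0.00615; adjusted p = 0.114 with an estimated correlation). They included ISL1, a LIM homeobox gene of pharyngeal progenitors (5.48), the pharyngeal pouch factor PAX1 (3.66) and EYA1 (3.61), while PAX9 (-0.17), the thyroid and lung factor NKX2-1 (-0.13) and OTX2 (-0.04) did not pass. In the NODAL list 7 of 9 fell and 1 rose (mean -4.59, adjusted p = 2.91e-07), with NODAL itself at -6.39 and PMEPA1 at -5.70. Against DE that list also fell in PFG (6 of 9 fell, 1 rose, mean -4.07, limma camera adjusted p = 1.65e-06) and MHG (6 of 9 fell, 1 rose, mean -3.56, adjusted p = 9.41e-06). Of 18 definitive endoderm genes 12 fell and 1 rose (adjusted p = 7.42e-07; adjusted p = 0.073 with an estimated correlation), SOX17 at -6.69 and HHEX at -4.72. Of 18 pluripotency genes 8 fell, GDF3 (-3.51) after NANOG, and SOX2, which is also a foregut factor, rose (1.57), with list adjusted p = 2.59e-05. The pluripotency list also fell against DE in PFG (10 of 18 fell, 1 rose, limma camera adjusted p = 1.6e-06) and MHG (13 of 18 fell, 0 rose, adjusted p = 5.69e-10). Of 17 neural ectoderm genes 7 rose, SIX3, an eye and forebrain homeobox gene (5.21), MAP2 (4.48), LHX2 (4.39) and PAX6 (2.50) first (mean 1.29, adjusted p = 0.00325; adjusted p = 0.0867 with an estimated correlation). SOX1 (-0.56) and ZIC1 (-0.14) of that list did not pass. Of 15 trophoblast genes 3 rose (adjusted p = 0.0473; adjusted p = 0.131 with an estimated correlation).

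In posterior foregut against DE, 7 of 10 retinoic acid response genes and 5 of 8 HOX genes of paralogs 1 to 4 rose. MEIS2, a HOX cofactor, was highest (8.17, SE 0.17), then the IGF-binding protein genes IGFBP5 (7.43, SE 0.26) and IGFBP3 (6.89), the basement membrane gene NID2 (6.86) and CA4, a carbonic anhydrase (6.80). CER1 (-8.86), ERBB4 (-8.61), LEFTY1 (-8.51), PLSCR2 (-8.35) and EOMES (-7.76) fell most. The test called 1097 genes higher and 845 lower.

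The posterior foregut list itself was not called (limma camera adjusted p = 0.119, mean 0.49). Of its 18 genes 6 rose and 1 fell: the fall was HHEX, a liver and pancreas homeobox gene (-6.05), and the plasma protein genes TTR (3.38) and APOA1 (3.22) and the factors SOX9 (2.53) and MNX1 (2.42) rose, while PROX1 (-0.06), PDX1, the pancreas factor (0.03), and the albumin gene ALB (-0.14) did not pass. Of 10 retinoic acid response genes 7 rose (mean 1.99, adjusted p = 1.4e-05), CRABP2 (4.66), DHRS3 (4.39) and the receptor RARB (3.37) first. CYP26A1 (-0.76) and CYP26B1 (-0.11), which degrade retinoic acid, did not pass, and the probe sets of CYP26B1 disagreed, their mean giving a called change of 1.82. Of 8 HOX genes of paralogs 1 to 4, 5 rose (adjusted p = 3.64e-05), led by HOXB3 (4.55) and HOXD1 (3.04), with HOXB4 at -0.14 not passing. That rise was not particular to PFG: in MHG against DE all 8 rose (mean 4.11, limma camera adjusted p = 5.69e-10). In the definitive endoderm list 9 of 18 fell, SOX17 by 6.03, and FOXA1 rose (2.68), with adjusted p = 5.23e-05 and adjusted p = 0.166 with an estimated correlation.

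Midgut/hindgut against DE raised all 8 measured HOX genes of paralogs 5 to 8, and 11 of 14 WNT response genes rose while 2 fell. In all, 939 genes were higher and 1142 lower. HOXC6 (9.27, SE 0.12), the WNT receptor FZD10 (8.52, SE 0.12), HOXB3 (8.29), the mesenchymal cadherin CDH11 (8.24), the WNT effector LEF1 (7.74) and the ligand WNT5A (7.42) rose most. LEFTY1 (-10.11, SE 0.17), PLSCR2 (-8.42), CER1 (-8.33), NANOG (-8.09) and ERBB4 (-7.97) fell most.

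Of 13 midgut and hindgut genes 5 rose and 1 fell, and the list narrowly missed the threshold (mean 0.95, limma camera adjusted p = 0.0511). CDX2, an intestinal factor (4.34), TBXT (3.53), CDX4 (3.18), the cadherin CDH17 (2.52) and CDX1 (1.99) rose, LGR5 fell (-2.17), and VIL1 (0.85), KRT20 (0.20) and ISX (0.05) did not pass. Leaving out any 1 of the DE or MHG arrays except DE replicate 3 put the list past the threshold (adjusted p from 0.0369 to 0.0472 in those 5 fits), but 6 other settings left it uncalled, from 0.0575 with array weights to 0.106 with only the 6 arrays and 0.116 with an estimated correlation. All 8 measured HOX genes of paralogs 5 to 8 rose (mean 3.73, adjusted p = 1.13e-08), HOXB8 by 5.30 and HOXB6 by 5.24. Of 12 genes of paralogs 9 to 13, 5 rose (adjusted p = 0.00188), HOXB9 (5.48) and HOXC9 (2.63) first, with HOXD12 (-0.01) and HOXB13 (0.11) among those that did not pass. Of 14 WNT response genes 11 rose and 2 fell (mean 2.20, adjusted p = 4.28e-07), TNFRSF19 at 5.12, SP8 at 4.12 and DKK4 at -4.02. Definitive endoderm genes fell in 14 of 18 and rose in 1 (adjusted p = 5.69e-10), SHISA2 by 6.49 and HHEX by 6.13. Markers of another lineage moved with this group: 10 of 19 mesoderm genes rose and 1 fell (mean 2.01, adjusted p = 8.11e-07), and 6 of 13 mesenchymal genes rose (adjusted p = 0.00224; adjusted p = 0.0516 with an estimated correlation).

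Anterior and posterior foregut were compared directly at day 7. SIX3 (7.25, SE 0.15), PCDH8 (6.54, SE 0.23), ISL1 (5.58), JAKMIP2-AS1 (5.21) and FAM241A (5.14) were higher in AFG. SKAP2 (-6.55, SE 0.09), CA4 (-5.88), the DNA sensor IFI16 (-5.82), APOA2 (-5.79) and ALKAL2 (-5.48) were higher in PFG. The test called 419 genes higher and 581 lower in AFG.

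The anterior foregut list was higher in AFG (6 of 11 rose, mean 2.11, limma camera adjusted p = 5.05e-07), with ISL1, HESX1 (4.72) and the head factor OTX2 (3.97) first and SOX2 (0.18), PAX9 (0.18) and NKX2-1 (-0.02) not passing. In the posterior foregut list 7 of 18 fell and 3 rose (adjusted p = 0.00438; adjusted p = 0.191 with an estimated correlation). MNX1 (-4.34) and APOA1 (-3.49) fell, and RBP4, the retinol carrier (2.66), SOX9 (1.42) and HHEX (1.32) rose. HOX paralogs 1 to 4 fell in 4 of 8 genes (adjusted p = 2.32e-10), HOXB3 by 4.83 and HOXD1 by 3.27. Retinoic acid response genes fell in 7 of 10 (adjusted p = 9.47e-13), DHRS3 by 3.82 and HOXB1 by 2.59. In the BMP response list 6 of 12 rose and MSX1 fell (-1.31), with GREM1, a BMP antagonist, at 3.26 and SMAD9 at 2.99 (adjusted p = 1.41e-06; adjusted p = 0.134 with an estimated correlation).

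Midgut/hindgut against posterior foregut again set HOXC6 first (9.22, SE 0.12), followed by DKK1 (8.42, SE 0.13), MSX1, a BMP-induced homeobox gene (6.81), HOXB-AS3 (6.70) and FZD10 (6.69). IGFBP5 (-6.51, SE 0.26), CA4 (-6.23), the natriuretic peptide gene NPPB (-5.68), TNFSF15 (-5.55) and PROK2 (-5.50) were lower. The test called 528 genes higher and 1000 lower.

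The midgut and hindgut list gained 7 of 13 and lost 2 (mean 1.39, limma camera adjusted p = 0.000415), CDX2 at 4.62, TBXT at 4.32, CDX4 at 3.49, ISX at -2.15 and TFF3 at -1.65, with VIL1 (-0.01) not passing. In the posterior foregut list 6 of 18 fell, TTR (-3.24) and ONECUT2 (-2.20) first, and TBX3 (4.50) and SOX9 (1.61) rose. Its adjusted p was 0.0208, with adjusted p = 0.166 with an estimated correlation, 0.132 without dim genes and 0.0737 after housekeeping scaling, so this call does not hold across settings. HOX paralogs 5 to 8 rose in 7 of 8 (adjusted p = 1.03e-10), HOXB8 by 5.47 after HOXC6, with HOXB5 (0.93) not passing. Paralogs 1 to 4 were also higher in MHG than in PFG (5 of 8 rose, 0 fell, mean 2.18, limma camera adjusted p = 1.54e-07). BMP response genes rose in 11 of 12 (mean 3.22, adjusted p = 9.42e-14). WNT response genes rose in 10 of 14 (adjusted p = 1.35e-12), LEF1 (6.62), SP5 (5.07) and APCDD1 (5.06) after DKK1, and 7 of 12 FGF and ERK response genes rose (adjusted p = 4.18e-07), SPRY4 (4.79) and IL17RD (3.95) first. Beside them, 9 of 19 mesoderm genes rose and 2 fell (adjusted p = 1.17e-06), 6 of 13 mesenchymal genes rose and 1 fell (adjusted p = 0.000769), and 5 of 17 neural ectoderm genes fell (adjusted p = 0.00219; adjusted p = 0.0663 with an estimated correlation).

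At the 2 ends of the gut tube, MHG against AFG, HOXC6 (9.44, SE 0.12), FZD10 (8.72, SE 0.12), HOXB3 (8.57), MSX1 (8.12) and HOXB-AS3 (6.79) were higher in MHG. SIX3 (-7.20, SE 0.15), SHISA2 (-7.11), FAM241A (-6.45), PAPLN (-6.41) and IRX1 (-6.15) were lower. The test called 529 genes higher and 792 lower. All 8 measured HOX genes of paralogs 1 to 4 rose (mean 4.28, limma camera adjusted p = 3.42e-13), HOXD1 by 5.09, as did all 8 of paralogs 5 to 8 (mean 3.83, adjusted p = 9.06e-12), HOXB8 by 5.41. The midgut and hindgut list rose in 7 of 13 (adjusted p = 6.36e-07), CDX2 at 4.83 and TBXT at 4.32, and the anterior foregut list fell in 7 of 11 (adjusted p = 5.89e-06), SOX2 at -4.71, HESX1 at -4.52 and OTX2 at -4.00. The trophoblast list was not called (2 rose, 3 fell of 15, adjusted p = 0.357), and its mean of 0.07 and median of -0.39 differ in sign. Its HAND1 rose (2.81) and TFAP2C fell (-1.58). Of other cell types, 10 of 19 mesoderm genes rose and 1 fell (adjusted p = 4.12e-07), 6 of 13 mesenchymal genes rose (adjusted p = 0.000709), and 8 of 17 neural ectoderm genes fell (adjusted p = 4.48e-07).

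Genes called higher in 1 day 7 population than in both others numbered 244 for AFG, 417 for PFG and 358 for MHG. By the smaller of the 2 fold changes, SIX3 (7.20), JAKMIP2-AS1 (5.21) and FAM241A (5.14) led in AFG, CA4 (5.88), ALKAL2 (5.41) and PROK2 (5.27) in PFG, and HOXC6 (9.22), MSX1 (6.81) and HOXB-AS3 (6.70) in MHG.

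Among the day 3 protocols, AFBLy cells had 11 of 19 mesoderm genes higher and 10 of 14 epithelial genes lower than DE. CDH11 (7.45, SE 0.18), the adhesion gene CHL1 (7.12, SE 0.07), HAPLN1 (6.50), FRMD4B (6.29), ALPK2 (6.25) and the apelin receptor APLNR (5.90) were highest. MOBP (-5.97, SE 0.14), APELA (-5.85), VHRT (-5.68), APOA2 (-5.31) and CFAP95 (-5.19) were lowest. The test called 588 genes higher and 835 lower, and housekeeping scaling moved the median of all genes from -0.03 to -0.13.

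Of 19 mesoderm genes 11 rose and 0 fell (limma camera adjusted p = 1.49e-09): HAND1 (5.33), SNAI2 and FOXF1 (3.42) rose, and TWIST1 (0.00), TBX20 (0.14) and NKX2-5 (0.15) did not pass. Of 12 BMP response genes 10 rose and GREM1 fell (-1.04), MSX1 at 5.38 and MSX2 at 5.13 (adjusted p = 2.19e-10). Of 18 definitive endoderm genes 9 fell and 2 rose (mean -0.65, adjusted p = 0.000987; adjusted p = 0.279 with an estimated correlation). LEFTY1 (-2.67), STC1 (-2.60), SHISA2 (-2.46) and EPCAM (-2.17) fell, RIPPLY1 (5.23) and GATA4 (1.81) rose, and SOX17 (-0.05) and CER1 (-0.25) did not pass. Pluripotency genes fell in 9 of 18 and VRTN rose (1.53), with SOX2 at -4.11 and NANOG at -4.06 (adjusted p = 9.62e-08). The endothelial and blood list had 0 of 10 changed in the limma test, with ETV2 at 0.67 and TEK at 0.55 (adjusted p = 0.75, mean 0.10 but median -0.03). The trophoblast list was not called (2 rose, 1 fell of 15, adjusted p = 0.748, mean 0.35 but median -0.07), with HAND1 and GATA3 (2.55) as the 2 that rose and TFAP2C (-1.81) the 1 that fell. Epithelial genes fell in 10 of 14 (adjusted p = 6.09e-11).

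Serum cells against DE had 10 of 18 endoderm genes lower and 4 of 18 pluripotency genes higher, with both list calls lost at an estimated correlation (adjusted p = 0.0508 each). In all, 413 genes were higher and 351 lower. That majority turned with housekeeping scaling (360 higher, 384 lower). The tendon gene TNMD (3.52, SE 0.14), LRFN5 (3.10), the BMP target ID1 (3.08, SE 0.11), CD1D (3.02) and GPM6A (2.99) were highest. TNMD, LRFN5 and CD1D had also fallen from APS to DE (-3.17, -3.19 and -3.63). Their log2 means were 7.39, 7.39 and 7.47 in APS and 7.73, 7.30 and 6.86 in Serum. The chemokine gene XCL1 (-5.05, SE 0.12), the trypsinogen gene PRSS2 (-4.63), ERBB4 (-4.48), the angiopoietin gene ANGPT2 (-4.30) and PLSCR2 (-4.24) were lowest. Averaging each gene's probe sets lowered the total from 764 to 499 (243 higher, 256 lower), and leaving out DE replicate 1 and Serum replicate 3 together, an alternative chosen after seeing the data, gave 830.

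Of 18 definitive endoderm genes 10 fell and 0 rose (mean -1.18, limma camera adjusted p = 1.73e-08; adjusted p = 0.0508 with an estimated correlation). SHISA2 (-3.11), CXCR4 (-2.58) and HHEX (-2.26) fell, while SOX17 (-0.98) and EPCAM (-0.36) did not pass. Of 18 pluripotency genes 4 rose, GDF3 (1.61), DPPA2 (1.60), PRDM14 (1.24) and FOXD3 (1.20), and NANOG (0.61) and LIN28A (-0.09) did not pass (mean 0.60, adjusted p = 2.97e-05; adjusted p = 0.0508 with an estimated correlation). Of 19 mesoderm genes 5 rose, APLNR (2.78) and WNT5A (2.24) first (adjusted p = 0.000485). In the neural ectoderm list SIX3 (-1.71) and HESX1 (-1.29) fell and SOX3 rose (1.17), while DHCR7 (-0.47) and INSIG1 (-0.32) of cholesterol synthesis and COL6A3 (0.92) of the fibroblast list did not pass. The neural ectoderm (1 rose, 2 fell of 17, adjusted p = 0.66), cholesterol synthesis (0 of 14 changed, adjusted p = 0.38) and fibroblast lists (COL1A2 rose by 1.60, adjusted p = 0.0976) were not called by limma camera.

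Serum against AFBLy, the 2 alternative protocols, called 1022 genes higher and 715 lower in Serum. APELA (7.04, SE 0.22), CFAP95 (6.10), VHRT (5.57), HLA-DPB2 (5.50) and GALNT3 (5.45) were highest, and CLSTN2 (-5.99, SE 0.11), CDH11 (-5.88), FRMD4B (-5.26), MSX1 (-5.14) and ANGPT2 (-4.97) lowest. Mesoderm genes fell in 10 of 19 and TWIST1 rose (1.11), HAND1 at -4.33, SNAI2 at -4.05 and FOXF1 at -3.25 (mean -1.36, limma camera adjusted p = 2.02e-05). Pluripotency genes rose in 10 of 18, SOX2 by 5.08 and NANOG by 4.67 (adjusted p = 1.81e-10). The definitive endoderm list was not called (3 rose, 7 fell of 18, adjusted p = 0.331): RIPPLY1 (-4.75) and GATA4 (-2.23) fell and LEFTY1 (1.95) and EPCAM (1.81) rose, with FOXA1 (0.12) and FOXA2 (0.27) not passing. The BMP list was not called either (2 rose, 5 fell of 12, adjusted p = 0.0714), with NOG at -4.51, MSX2 at -4.17 and GREM1 at 3.34. Mesenchymal genes fell in 7 of 13 and rose in 1 (adjusted p = 0.000174), and epithelial genes rose in 10 of 14 and fell in 1 (adjusted p = 2.02e-05; adjusted p = 0.106 with an estimated correlation).

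Genes called higher under 1 day 3 protocol than under both others numbered 159 for DE, 425 for AFBLy and 271 for Serum. XCL1 (5.05), CCDC141 (3.76) and CST1 (3.68) led for DE, CDH11 (5.88), CLSTN2 (5.84) and FRMD4B (5.26) for AFBLy, and TNMD (3.52), ACTA1 (2.86) and FGF4 (2.83) for Serum. These hold among day 3 protocols only: ACTA1 was higher in hESC (log2 mean 10.37, Serum 8.05) and FGF4 in APS (10.99, Serum 7.29). Averaging each gene's probe sets lowered the Serum count from 271 to 160.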

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

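The alternatives were planned before the data were examined, except leaving out DE replicate 1 and Serum replicate 3 together. An adjusted p under 0.01 cannot change a count, since 0 genes past the fold threshold had an adjusted p of 0.01 or more. The trended robust prior and the replicate block estimate the variance anew and could have dropped a gene, but changed no count either: with the block the highest adjusted p past the fold threshold was 0.0102. The fit on only the 6 arrays dropped 1 gene, to 788 in APS against hESC. With so few genes near the p threshold, these matching counts say little about stability. The replicate numbers do not pair the arrays (12 of 84 same-numbered pairs correlate over 0.1, median 0.0136). The replicate block lowered total degrees of freedom from 20.6 to 18.6, left every fold change as it was in this balanced design, and called 789 genes in APS against hESC and 764 in Serum against DE, the same genes as without it in all 11 comparisons.

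Without a fold threshold the counts were 6322 (APS against hESC), 8683 (DE against APS), 10411 (AFG against DE), 9723 (PFG against DE), 9473 (MHG against DE), 5473 (AFG against PFG), 7911 (MHG against PFG), 8031 (MHG against AFG), 8179 (AFBLy against DE), 8285 (Serum against DE) and 8948 (Serum against AFBLy). Genes marking a population or protocol became 1521 (AFG), 1597 (PFG), 2644 (MHG), 1721 (DE), 2690 (AFBLy) and 2379 (Serum). Which direction held more genes turned in 10 of the 11 comparisons, AFBLy against DE excepted: DE against APS went from 651 higher and 429 lower to 4014 and 4669, and APS against hESC from 306 and 483 to 3240 and 3082. The dropped threshold is itself the cause. With the mean of each gene's probe sets, Serum against DE called 499 genes (243 higher, 256 lower), 160 marked Serum, and CYP26B1 turned from -0.11 to a called 1.82 in PFG against DE. The cause was not tested.

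Among the lists named for the populations compared, calls lost with an estimated correlation were anterior foregut in AFG against DE (mean 1.53, adjusted p = 0.114), posterior foregut in AFG against PFG (-0.89, 0.191) and MHG against PFG (-0.51, 0.166), definitive endoderm in AFBLy against DE (-0.65, 0.279), and in Serum against DE definitive endoderm (-1.18, 0.0508) and pluripotency (0.60, 0.0508); the wider correlation itself is the cause. Posterior foregut in MHG against PFG was also lost without dim genes (-0.53, adjusted p = 0.132) and after housekeeping scaling (-0.60, 0.0737). Midgut and hindgut in MHG against DE gained its call with averaged probe sets (0.91, adjusted p = 0.0272), housekeeping scaling (0.86, 0.0249), the trended robust prior (0.95, 0.0487) and the 2 doubted arrays left out (0.95, 0.0484), and stayed uncalled with an estimated correlation (adjusted p = 0.116), only the 6 arrays compared (0.106), dim genes left out (0.0878), the replicate block (0.0669), another quantile normalization (0.0654) and array weights (0.0575). With 1 array left out it ran from 0.90 to 0.97 (adjusted p from 0.0369 to 0.0522). The cause was not tested.

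With 1 array left out, all 141 counts stayed within 1.5 times, from 734 (without DE replicate 2) to 799 (without DE replicate 1) for Serum against DE, and 97 list results kept their side of the threshold and 5 gained a call. Of the named gene results, 36 lost and 30 gained a call. In the other settings 8677 kept their side of the threshold, 79 lost a call, 27 gained a call and 1 reversed. Signal near the background limits folds against dim groups, which RMA compresses.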

Other observations

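The test of the mixture with streak cells, that of scaling for Serum and the lists named in this paragraph were chosen after the result was seen. Cell cycle genes were lower in DE than in APS (3 of 18 fell, mean -0.87, limma camera adjusted p = 3.2e-15) and their mean level was lowest in DE of all 8 groups (9.60), so the list was also higher than in DE, with few genes passing, in Serum (1 of 18 rose, mean 0.62, adjusted p = 4.23e-14), AFG (4 of 18, 0.66, 6.15e-09) and MHG (4 of 18, 0.66, 2.24e-08). The same held in PFG (3 of 18, mean 0.56, adjusted p = 4.12e-07) and AFBLy (2 of 18, mean 0.34, adjusted p = 0.000413), both lost with an estimated correlation (adjusted p = 0.0704 and 0.271). Stress response genes rose in 6 of 13 and fell in 1 from APS to DE (adjusted p = 3.1e-05, and 0.141 with an estimated correlation) and fell in 9 of 13 and rose in 1 in MHG against DE (adjusted p = 4.28e-07). Their mean level was highest in DE of all 8 groups (9.41). Against DE the list was also lower in AFG (7 of 13 fell, 1 rose, limma camera adjusted p = 0.000211) and PFG (5 fell, 1 rose, 0.000748). The same held in AFBLy (7 fell, 2 rose, 0.0167) and Serum (5 fell, 0 rose, 4.28e-05). With an estimated correlation these calls were lost (adjusted p = 0.125 in AFG, 0.196 in PFG, 0.412 in AFBLy and 0.096 in Serum). FGF and ERK response genes fell in 9 of 12 and rose in 1 in AFG against DE (mean -1.51, adjusted p = 8.47e-06) and in 8 of 12 in PFG against DE (mean -2.13, adjusted p = 2.29e-07). BMP response genes rose in 10 of 12 in MHG against DE (mean 3.28, adjusted p = 5.59e-09) and in 6 of 12 in Serum against DE (mean 1.21, adjusted p = 1.73e-08; adjusted p = 0.0508 with an estimated correlation). Mesenchymal genes rose in 6 of 13 and fell in 1 in AFBLy against DE (adjusted p = 5.45e-05).

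In AFG 7 of 17 neural ectoderm genes rose over DE, a list call lost with an estimated correlation (adjusted p = 0.0867), and admixed neural cells may be a source. This and the later bootstrap intervals resample genes of the same arrays, so they do not measure the spread between cultures. A separate list of neural cell transcripts, written before its values were seen, had a median of -0.093 in AFG against PFG (95% bootstrap over genes -0.16 to 0.40), below the bound of 0.5 set to argue against such cells. That bound was badly chosen, because cells present in both populations cancel: against DE, 7 of 17 transcripts rose in AFG, FABP7 by 4.75, DLL1 by 3.74, NRCAM by 3.67 and SOX11 by 3.39, and 1 fell, STMN2 (-3.60), with a list median of -0.15. DLL1 is not particular to AFG, since it rose more over DE in PFG (5.76) and MHG (6.56). The neural genes ELAVL3 (-0.30), ELAVL4 (-0.15) and HES5 (-0.34) did not pass in AFG against DE. After the rises over DE were seen the rule was made stricter, asking also for no rise over DE, which turned the label from arguing against such cells to undecided, so neural cells and foregut cells expressing these genes cannot be told apart here.

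In MHG 10 of 19 mesoderm genes rose over DE and 1 fell. Array scaling is argued against as the cause, since the list's mean was 1.93 after housekeeping scaling against 2.01 before. Admixed mesodermal cells may contribute: a separate list of their transcripts, written before its values were seen, had a median of 0.43 in MHG against PFG (95% bootstrap over genes -0.18 to 1.47), with 6 of 18 higher, FOXC2 (3.97), BGN (2.71) and COL5A2 (2.46) first, and TCF21 lower (-2.81). Against DE 4 rose, FOXC2 (2.44) and FBN2 (2.32) first, and 2 fell, COL6A2 (-1.79) and COL5A2 (-1.33), with a list median of 0.057. COL5A2 was thus higher in MHG than in PFG but lower than in DE. The interval spans both outcomes, so such cells and the MHG protocol's own effect cannot be told apart.

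Serum cells had 10 of 18 endoderm genes lower and 4 of 18 pluripotency genes higher than DE, and with an estimated correlation neither list was called (adjusted p = 0.0508 each). Scaling is argued against, since the endoderm list's mean was -1.23 after housekeeping scaling against -1.18. A mixture of stem cells and endoderm cells in 1 fraction would give genes rising and falling from hESC to DE the same DE-like fraction. On linear values the medians were 0.361 over 804 rising and 0.548 over 781 falling genes, a difference of -0.187 (95% bootstrap over genes -0.236 to -0.143). That interval straddles the absolute bound of 0.2 set beforehand. The quartiles ran from 0.163 to 0.617 for rising genes and from 0.323 to 0.753 for falling genes. A mixture in 1 fraction would hold all genes near 1 value, apart from measurement error and the compression by RMA. How far those would spread the genes was not estimated. This spread, a reading not set beforehand, would therefore go against such a mixture only if they spread genes less. A mixture that includes streak cells allows no gene above all 3 sources, yet 17 of 413 genes (4.1%) were, each with an adjusted p of at most 0.000275, CHL1, CCNA1 and ALPK2 first, which argues against those 3 sources as the whole difference; the bound of 5% set after the result was too lax, since no such gene is allowed, and the rule was changed for that reason. Of the 17 genes 7 were called higher still in AFBLy, so another cell type stays open. Of the 36 endoderm and pluripotency list genes 0 were called outside the range of the 3 sources, which leaves open a share of stem cells for these genes. For them a mixture of the 3 sources and an intermediate state cannot be told apart.

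Other splits of the 6 arrays of each comparison number 10 with the real one, too few for a share under 0.05, and in each of the 11 comparisons 1 split, the real one, gave as many genes. Every split but the real one puts arrays of both groups on each side, which shrinks the difference and widens the spread. Low counts there follow from any large difference between groups, so they cannot decide on chance. The highest other split called 1 gene in PFG against DE (real 1942) and MHG against PFG (real 1528), and 0 in the rest, whose real counts were 789 (APS against hESC), 1080 (DE against APS), 1936 (AFG against DE), 2081 (MHG against DE), 1000 (AFG against PFG), 1321 (MHG against AFG), 1423 (AFBLy against DE), 764 (Serum against DE) and 1737 (Serum against AFBLy).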
